A study of Mus musculus with 10 samples.

How the data were processed

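Tumour-associated macrophages were isolated by fluorescence-activated cell sorting, and per the labels' protocols their mRNA was copied to cDNA with the SMART-Seq v4 low-input kit and amplified by 16 PCR cycles. Libraries were made from sheared cDNA with a ThruPLEX kit, which does not mark strand, and all 10 were sequenced in 1 single-read run of 75 cycles on a NextSeq 500. Reads of antisense or overlapping genes therefore cannot be told apart. The submitters' processing notes name the aligner STAR, the quantifier RSEM and the mm10 build, without versions or order. The annotation and the normalisation tool are not given in the sources used here. The libraries carry no molecular identifiers, so reads after amplification are not independent molecules.

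The authors deposited 1 table per library with a gene symbol, an Ensembl gene ID and a value. No header or label states the unit. The values have a decimal comma, start at 0, and after undoing log2(value + 1) fall on equal steps within each library. The deposited values were therefore read as log2 of the read count divided by a library size factor, plus a pseudocount of 1. Dividing by the step recovered whole reads, within a tolerance of 0.01 of a read, for 100% of the values in every library. The totals of these reads are the depths given. Every gene ID matched the GENCODE M21 annotation of GRCm38, the assembly also called mm10, and all were protein-coding with no gene encoded by mitochondria. Coordinates are from that annotation. For 14 genes the symbol had been turned into a date and was restored from the ID, and 27 symbols stood on 2 IDs, which were kept apart. Members of gene families with near-identical sequences, such as the MHC genes and the chitinase-like gene Chil3, may share reads, and their values are uncertain to that extent.

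A quasi-likelihood test on counts had been planned as the main test, with a second count model as an alternative. Neither was run, because the plan named a fallback for files without counts and the deposited values are on a log2 scale. The recovered reads would have allowed both. The fallback written before the data were examined was used: limma-trend on the deposited log2 values, fitted in limma 3.58.1 under R 4.3.3, with robust empirical Bayes moderation carried over from the planned test. Genes with at least 10 recovered reads in at least 3 libraries were kept, which left 11564; this filter took the place of the automatic one planned for counts. All 10 libraries entered 1 fit with a mean per group and no covariate, since the labels give no batch, pairing or sex. Tests were two-sided, and Benjamini-Hochberg adjusted p below 0.05 counted as past the threshold. Fold changes are on the log2(normalised reads + 1) scale and understate the change of low genes. Means ± SD are of the log2 values over libraries.

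Before the data were examined, 20 lists of macrophage and cell programs and 11 marker lists of other cell types were fixed. The adipocyte list had 0 tested members, which left 30 lists. Lists were tested with limma's camera on the log2 values, in place of the planned version for counts, at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists within each comparison. Beside the calls over all genes, members were also adjusted over the list alone, which does not correct over the 30 lists. Over the 3 comparisons the median, mean and camera direction differed in sign for 20 of 90 list results, 0 of them past the threshold.

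The genes named follow a rule fixed in advance. It takes Mertk, Axl, Tyro3, Gas6, Pros1, Ptdss1, Ptdss2 and Lyz2 in every comparison; up to 8 called genes per direction with at least 10 CPM of recovered reads in the higher group and ranges that do not overlap; where fewer than 4 pass, the genes of smallest unadjusted p up to 4, as values; up to 4 members by smallest p of each list past camera and of both cell-cycle lists; and up to 6 genes per direction called in both comparisons with control. Gene models with automatic names were skipped, among them those named after a clone accession. Genes named for passing over a list alone, Spp1 in Ptdss1 knockdown, Fn1 in the direct comparison and Gm10260 were named after their values were seen. So were the markers Krt8, Krt18, Krt7, Erbb3, Cdh1 and Spint2.

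The alternatives written in advance were recomputed median-of-ratios or upper-quartile factors, no filter, a stricter filter of 50 reads in 3 libraries, limma-voom on the recovered reads, no robust moderation, only the compared groups in the fit, a threshold of 0.1, a test against a fold of 1.2, thinning to the smallest total, and leaving out each library. Chosen after seeing the data were library weights, voom with quality weights or scaled by totals, leaving out control replicate 2 and Ptdss1 knockdown replicate 1 together, the number of detected genes as a covariate, a pseudocount of 8, only genes with 10 reads in all 10 libraries, and camera with an estimated correlation without Ptdss1 knockdown replicate 1. Chance agreement through the shared controls was taken from 100 simulated draws in which the residuals of the libraries were shuffled around a common mean, since 3 control libraries are too few to give each comparison its own 2.

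The test was checked on reads simulated from the real means and size factors over 11564 genes, with 200 genes changed. With the spread of the data, the comparison of Mertk KO with control recovered 0% of genes changed 2-fold, 4% of those changed 4-fold, 18% of those changed 8-fold and 26% of those changed 16-fold. For Ptdss1 knockdown against control the shares were 0%, 4%, 26% and 36%. Each gene was given 1 spread in all libraries, so a trait of a single library was not reproduced. The shares therefore do not rank the power of the 2 comparisons. Of 11317 unchanged genes, 4 were called in each comparison. From the 2-fold to the 16-fold change, 0, 2, 9 and 13 of 50 changed genes were called for Mertk KO. For Ptdss1 knockdown these were 0, 2, 13 and 18. The 4 false calls are thus few among the unchanged genes but not few among the calls. A mitosis list lowered 2-fold passed camera in both, with adjusted p of 0.00336 and 0.000187, and 0 other lists were called. Each gene was drawn independently, so the simulation does not check camera on lists whose members vary together. With a low dispersion of 0.05, 98% and 100% of the genes changed 4-fold were recovered, and 10 and 8 unchanged genes were called. The median SE of a log2 fold change was 1.28 for Mertk KO against control and 1.37 for Ptdss1 knockdown against control. Among the 2404 genes with a mean log2 value above 10 it was 0.501 and 0.535. The recovered shares pool genes of all levels and were not taken for these genes alone.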

Results

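Gene expression was measured by RNA sequencing in tumour-associated macrophages sorted from mouse mammary tumours 5 weeks after PyMT mammary tumour cells had been injected into 2 mammary glands of each animal. PyMT cells come from mammary tumours driven by the polyoma middle T oncogene, and all mice were C57BL/6. Mertk is a receptor tyrosine kinase through which macrophages take up apoptotic cells. Ptdss1 encodes a phosphatidylserine synthase, and exposed phosphatidylserine is the lipid by which apoptotic cells are recognised. The control group held 3 libraries from wild-type mice with wild-type tumour cells. The Mertk KO group held 4 libraries from mice labelled as Mertk knockouts of the macrophages, also with wild-type tumour cells. The Ptdss1 knockdown group held 3 libraries from wild-type mice whose tumour cells carried the knockdown. The comparisons ask how losing the receptor on the macrophage, or lowering the synthase in the tumour cell, goes with the state of the macrophages. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between libraries, which may in part be technical.

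The reads assigned to genes came to 19789413, 14622749 and 24260871 in the 3 control libraries, to 10292592, 19121396, 19214285 and 21321858 in the 4 Mertk KO libraries, and to 23442827, 15927269 and 25815071 in the 3 Ptdss1 knockdown libraries. The number of genes with at least 10 reads did not follow this depth. Ptdss1 knockdown replicate 1 had 6995 such genes and control replicate 2 had 9066, while Mertk KO replicate 1, with the lowest total, had 10727. Of the genes with at least 10 reads in 7 or more of the other libraries, 31.5% were below 10 reads in Ptdss1 knockdown replicate 1, 13.1% in control replicate 2, 8.60% in Mertk KO replicate 3 and 5.75% in Mertk KO replicate 4. The remaining libraries missed between 0.108% and 1.28%. The first principal component, with 41.3% of the variance, set Ptdss1 knockdown replicate 1 apart from all other libraries, and the second, with 17.9%, set control replicate 2 apart. Neither component separated the groups.

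**Figure D1:**
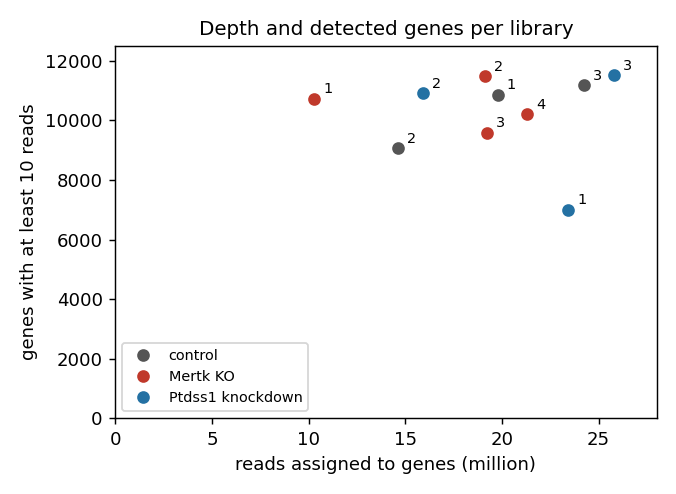
Each point is 1 library, numbered by replicate and coloured by group, with the reads assigned to genes on the x axis and the number of genes with at least 10 reads on the y axis. Ptdss1 knockdown replicate 1 lies lowest, at 6995 genes from 23442827 reads.

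Mertk itself (chromosome 2, 128698956 to 128802894, plus strand, GRCm38) was read in every library. Its normalised level on the log2 scale was 9.64, 9.26 and 10.97 in the 3 control libraries, 10.63, 9.72, 9.25 and 8.95 in the 4 Mertk KO libraries, and between 7.47 and 10.20 in the 3 Ptdss1 knockdown libraries. The mean was 9.96 ± 0.90 (SD, n = 3) in control and 9.64 ± 0.74 (SD, n = 4) in Mertk KO, a log2 fold change of -0.32 with an SE of 0.70 (limma adjusted p = 1.0), which was 0.19 without control replicate 3. The labels do not state which part of the gene was deleted, and a value for the whole gene can stay up when only some exons are removed, so these values do not check the labels. Ptdss1 (chromosome 13, 66932830 to 66998401, plus strand) was targeted in the tumour cells and not in the sorted macrophages. Its level in the macrophages was 9.43 and 9.58 in Ptdss1 knockdown replicates 2 and 3, against 9.73, 10.36 and 9.44 in control, while Ptdss1 knockdown replicate 1 had 3 reads of it. These values do not check the knockdown either.

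In the libraries labelled Mertk KO, 2 genes rose against control and none fell. Spp1, which encodes the secreted phosphoprotein osteopontin, rose by 3.23 on the log2 scale (SE 0.51, limma adjusted p = 0.0317), from 12.61 ± 0.31 (SD, n = 3) to 15.84 ± 1.18 (SD, n = 4). Fn1, which encodes the extracellular matrix protein fibronectin, rose by 2.23 (SE 0.35, limma adjusted p = 0.0317), from 12.67 ± 0.22 (SD, n = 3) to 14.90 ± 0.37 (SD, n = 4). Both genes were higher in 4 of 4 Mertk KO libraries than in any control library. They were also higher than in any control library in 3 of 3 Ptdss1 knockdown libraries, with Spp1 at 14.10 ± 0.48 (SD, n = 3) and Fn1 at 13.74 ± 0.12 (SD, n = 3), without passing there or in the direct comparison (limma adjusted p = 0.841 and 0.805 for each gene). Spp1 lies on the plus strand of chromosome 5 from 104435118 to 104441050, and Fn1 on the minus strand of chromosome 1 from 71585520 to 71653200. Among 11564 genes tested, 238 had an unadjusted limma p below 0.05. Evenly spread p-values would give 578. All 3 comparisons lay below that count, so it need not be the chance level of these data. Leaving out any of the 3 control libraries, or Mertk KO replicate 1, 2 or 3, left no gene past the threshold, with a limma adjusted p of Spp1 between 0.0515 and 0.426. None passed with upper-quartile factors, without a filter, with a stricter filter, against a fold of 1.2 or among genes detected in every library, while array weights gave 25 genes. Without both low-complexity libraries, Htra1 and Gm10260 passed and Spp1 and Fn1 did not. Without Mertk KO replicate 4 or without Ptdss1 knockdown replicate 3 Spp1 alone passed, without Ptdss1 knockdown replicate 1 there were 4 genes, with Htra1 and the gene model Gm10260 added. The fold changes stayed between 2.66 and 3.57 for Spp1 and between 2.10 and 2.37 for Fn1 when any 1 library was left out.

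**Figure D2:**
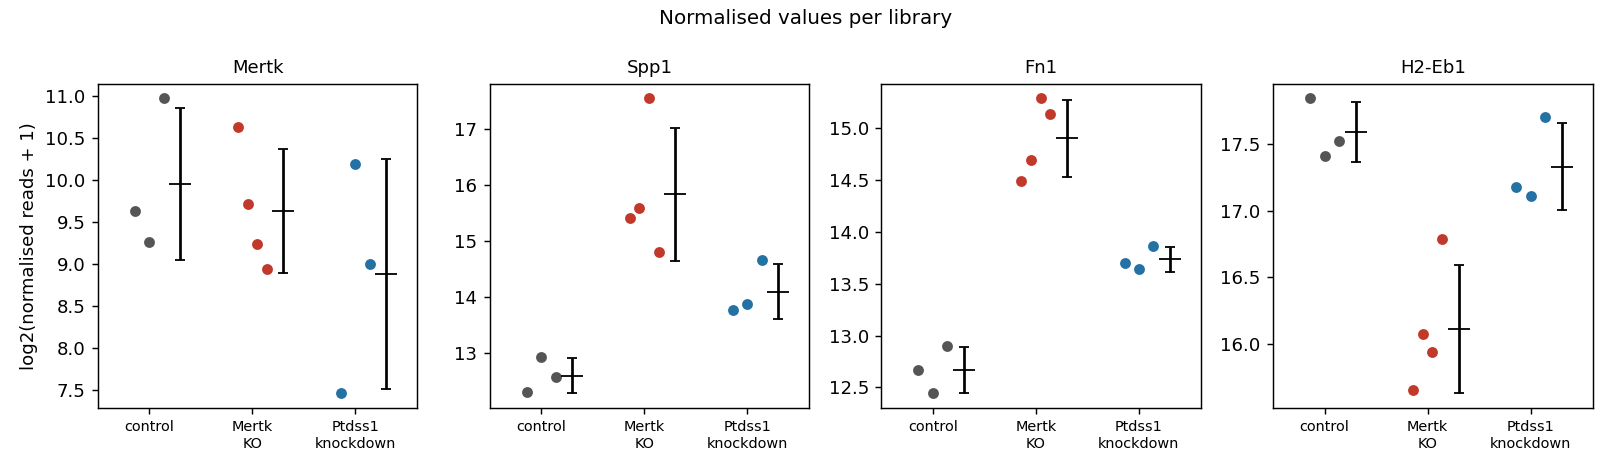
Each point is 1 library of the group on the x axis, and the y axis gives log2 of the normalised reads plus 1 for the gene named above each panel; the bar beside the points is the mean with the SD. All 4 Mertk KO libraries and all 3 Ptdss1 knockdown libraries lie above all 3 control libraries for Spp1 and Fn1, while the Mertk values of the groups overlap.

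The next genes by unadjusted p did not pass the threshold and are given as values. Htra1, a secreted serine protease, was at 8.60, 7.92, 10.15 and 9.28 in the 4 Mertk KO libraries and at 2.09, 0 and 0 in control (limma adjusted p = 0.712). Timp1, an inhibitor of matrix metalloproteinases, was at 9.91 ± 1.13 in Mertk KO and 6.60 ± 0.50 in control (limma adjusted p = 1.0). On the lower side, H2-Eb1, a chain of the MHC class II molecule, was at 16.11 ± 0.48 in Mertk KO and 17.59 ± 0.22 in control (limma adjusted p = 0.712). Crem, a transcription factor of the cAMP response, was at 9.24 ± 0.93 against 11.52 ± 0.38, and Il1r2, the decoy receptor for interleukin 1, at 4.57 ± 2.35 against 10.28 ± 1.76. Nek3, a kinase, was at 0.86 in Mertk KO replicate 2 and at 0 in the other Mertk KO libraries, against 3.81, 8.97 and 5.73 in control. Of the receptor's relatives and ligands, Axl had a log2 fold change of -1.26 (SE 0.53), Gas6 of 1.38 (SE 0.74) and Pros1 of 1.93 (SE 1.62), each with a limma adjusted p of 1.0, and Tyro3 was listed at 0 in all 10 libraries. Gas6 was at 0.88 without Mertk KO replicate 3 and Pros1 at 0.47 without control replicate 2. Of the phosphatidylserine synthases, Ptdss1 had a fold change of -0.90 (SE 1.42), which was -0.60 without Mertk KO replicate 1, and Ptdss2 of 3.31 (SE 1.69), which was 1.23 without control replicate 2, where it was listed at 0. Lyz2, the lysozyme gene of myeloid cells, differed by 0.33 (SE 0.33) and by -0.088 with array weights.

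Of 30 gene lists tested in this comparison, 10 passed camera, 7 toward higher and 3 toward lower values in Mertk KO. None of these 10 passed with an inter-gene correlation estimated from the data, and none passed the directional fry test. Without control replicate 1 the list of inflammatory cytokines alone passed, and the other 9 lists had adjusted p between 0.0633 and 0.867. The matrix remodelling and angiogenesis list had the lowest p with the estimated correlation. Its camera adjusted p was 0.000219, its adjusted p was 0.0702 with an estimated correlation, and 17 of its 21 members had positive fold changes. The median of the list was 0.59. Timp1, at 3.31 (SE 0.89), was its only member past the threshold when adjusted over the list alone, and none passed over all genes tested. Ecm1, an extracellular matrix protein, had a fold change of 1.74 (SE 0.57), Nrp2, a semaphorin and VEGF co-receptor, of 1.83 (SE 1.00), and Hbegf, a growth factor of the EGF family, of 2.91 (SE 1.60). The list of lipid-associated macrophage genes had a camera adjusted p of 0.00134 and an adjusted p of 0.329 with an estimated correlation. Its median log2 fold change was 0.29. Of its 14 members, Spp1 rose over all genes tested, and Spp1 and Fabp5 passed when adjusted over the list alone. Fabp5, a fatty acid binding protein, had a fold change of 1.82 (SE 0.55), which was 1.12 without control replicate 1, Gpnmb, a glycoprotein of lipid-laden macrophages, of 4.19 (SE 1.82), and Mmp12, the macrophage elastase, of 1.43 (SE 0.62). Mmp12 was at 0.59 without control replicate 1 and at 2.31 without control replicate 2.

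The alternative activation list passed camera (adjusted p = 0.00785, and adjusted p = 0.329 with an estimated correlation), with members on both sides. Chil3, a chitinase-like secreted protein, had a fold change of 4.53 (SE 1.91), Cd163, a haemoglobin scavenger receptor, of 5.15 (SE 2.16), and Pdcd1lg2, a ligand of PD-1, of 1.27 (SE 0.52), while Mgl2, a lectin, had one of -1.98 (SE 0.65). The lysosome list passed camera (adjusted p = 0.00785, and adjusted p = 0.701 with an estimated correlation), with 25 of 30 members positive, among them the cathepsins Ctsd at 1.36 (SE 0.49), Ctsl at 0.83 (SE 0.37) and Ctsb at 0.79 (SE 0.44), and the proton pump subunit Atp6v0d2 at 3.38 (SE 1.78). Without Mertk KO replicate 3 the adjusted p was 0.398 for alternative activation and 0.0751 for lysosome, and without replicate 4 it was 0.307 for lysosome. The glycolysis and hypoxia list passed camera (adjusted p = 0.00158, and adjusted p = 0.701 with an estimated correlation), with 22 of 24 members positive and the enzymes Tpi1 at 0.72 (SE 0.39), Gapdh at 0.58 (SE 0.39), Pkm at 0.66 (SE 0.49) and Eno1 at 0.58 (SE 0.46). The list of inflammatory cytokines passed camera (adjusted p = 0.0300, and adjusted p = 0.701 with an estimated correlation), with the chemokines Ccl7 at 1.17 (SE 0.75) and Ccl5 at 0.97 (SE 0.79), but had adjusted p of 0.978 without control replicate 3 and 0.678 without Mertk KO replicate 1. Without control replicate 1, Pdcd1lg2 was at 0.82, Atp6v0d2 at 1.98 and Pkm at 0.42, and without Mertk KO replicate 4, Ctsb was at 0.47. Eno1 was at 0.34 without Mertk KO replicate 3 or 4, Ccl7 at 0.24 without control replicate 3 and Ccl5 at 0.14 without Mertk KO replicate 1. No member of these 4 lists passed the threshold over all genes tested or when adjusted over the list alone. The members named are those of smallest p. The median log2 fold changes were 0.78 for alternative activation, 0.23 for lysosome, 0.44 for glycolysis and 0.37 for inflammatory cytokines. Without control replicate 1 the glycolysis median was 0.049.

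Genes of the cell cycle lay lower in Mertk KO than in control as lists, with no member past the threshold over all genes tested or when adjusted over the list alone. The mitosis list had a median log2 fold change of -1.44 over 47 members, of which 37 were negative (camera adjusted p = 4.34e-05, and adjusted p = 0.701 with an estimated correlation). The list of S phase and DNA replication had a median of -1.02 over 36 members, of which 28 were negative (camera adjusted p = 0.000109, and adjusted p = 0.701 with an estimated correlation). Aurkb, a mitotic kinase, had a fold change of -4.83 (SE 1.98), Top2a, the topoisomerase of dividing cells, of -2.53 (SE 1.42), and Nuf2 and Prc1, which act at the kinetochore and the spindle midzone, of -2.78 (SE 1.71) and -2.85 (SE 1.83). In the S phase list, Pole, the catalytic subunit of a replicative polymerase, had a fold change of -3.86 (SE 1.88), Rfc3, a clamp loader subunit, of -2.14 (limma adjusted p = 1.0), Ccne2, a cyclin, of -3.57 (SE 2.02), and Tyms, thymidylate synthase, of -3.39 (SE 1.99). The mean of the mitosis list was 7.92, 4.64 and 6.26 in the 3 control libraries and 5.23, 6.27, 5.63 and 2.92 in the 4 Mertk KO libraries, so the groups overlapped. Without control replicate 1, both lists had a camera adjusted p of 0.137, with medians of -0.63 for mitosis and -0.58 for S phase, and the mitosis median was -0.64 without Mertk KO replicate 4. Prc1 was at -1.88 and Rfc3 at -1.29 without Mertk KO replicate 3, and Tyms at -1.70 without Mertk KO replicate 4.

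Of 10 marker lists of other cells a macrophage sort could hold, 2 passed camera in this comparison, neither with an estimated correlation. Their members past the threshold over all genes tested came to 0. The NK cell list was lower in Mertk KO (camera adjusted p = 0.00134, and adjusted p = 0.329 with an estimated correlation), with all 6 tested members negative, Klrk1 at -2.08 (SE 0.77) and Nkg7 at -4.75 (SE 2.07). Its library means were 8.51, 3.24 and 6.59 in control and 6.65, 5.01, 1.68 and 1.51 in Mertk KO. The fibroblast list was higher (camera adjusted p = 0.0300, and adjusted p = 0.701 with an estimated correlation), and this came with 2 libraries: its mean was 6.62 in Mertk KO replicate 2 and 8.67 in replicate 4, against 1.15 and 0.81 in replicates 1 and 3 and 2.31, 0.89 and 3.11 in control. The camera adjusted p was 0.544 without Mertk KO replicate 4, 0.179 without Mertk KO replicate 2, 0.0749 without control replicate 2 and 0.113 without Ptdss1 knockdown replicate 1. Col1a1, a fibrillar collagen, had 1, 97, 2 and 495 reads in the 4 Mertk KO libraries and 2, 18 and 18 in control. The other 8 cell type lists had camera adjusted p between 0.0864 and 0.976, and the other 12 program lists lay in the same range. The list of macrophage identity genes had a camera adjusted p of 0.976. Of the 53 named genes tested in this comparison, 10 had a fold change nearer to 0 by over 1.5 times or of the other sign without Mertk KO replicate 4. This held for 8 without control replicate 1, 6 without Mertk KO replicate 3 and between 2 and 5 without each of the other 4 libraries compared.

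**Figure D3:**
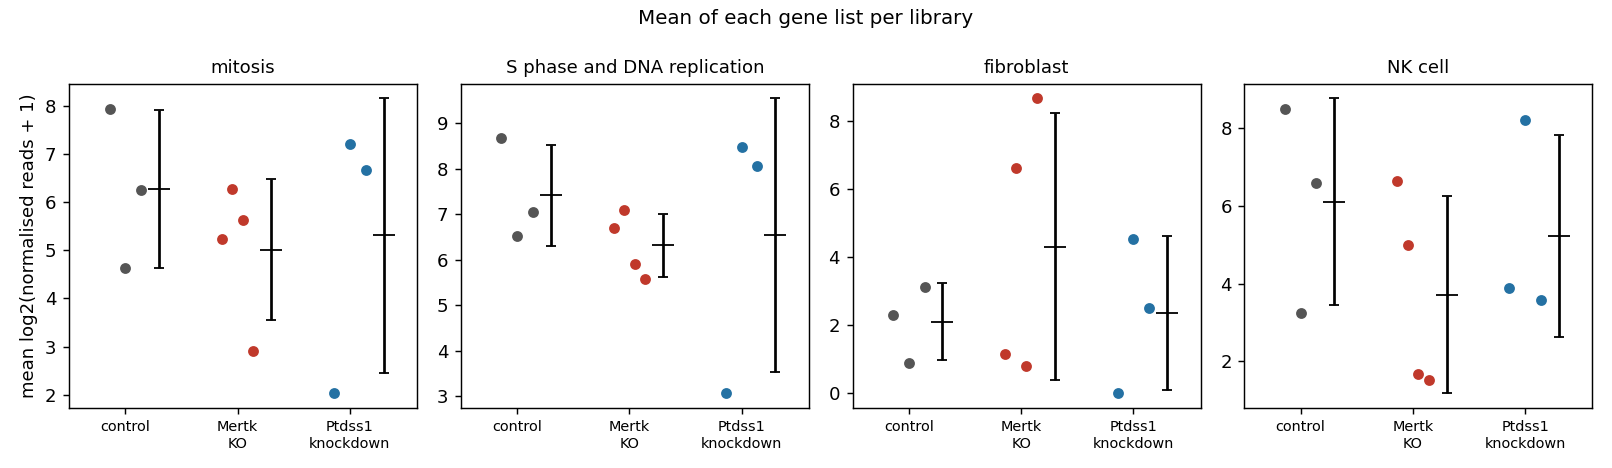
Each point is the mean log2 value of the tested members of a gene list in 1 library, by group on the x axis, with the group mean and SD beside the points. The mitosis means of Ptdss1 knockdown replicate 1 (2.04) and Mertk KO replicate 4 (2.92) lie lowest, and the fibroblast means of Mertk KO replicates 4 (8.67) and 2 (6.62) lie highest.

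In macrophages from tumours with the Ptdss1 knockdown, no gene rose or fell against control in limma. The smallest limma adjusted p was 0.841, and 335 of 11564 genes had an unadjusted p below 0.05, where evenly spread p-values would give 578. Voom gave 0 calls on either scaling and with quality weights, array weights gave 2, and every other setting tried gave 0. The genes with the smallest unadjusted p are given as values. Mmp12, the macrophage elastase, was at 13.36 ± 0.64 (SD, n = 3) against 10.95 ± 1.73 (SD, n = 3) in control, a log2 fold change of 2.41 (SE 0.67), and passed when adjusted over the lipid-associated list alone. Rsc1a1 and Trim46 were listed at 0 in all 3 control libraries. In the 3 knockdown libraries Rsc1a1 was at 10.35, 4.67 and 7.52 and Trim46 at 10.75, 4.87 and 3.92, and Bex6 was at 10.18, 4.67 and 4.32 against 0, 0 and 0.79 in control, each highest in the low-complexity replicate 1. On the lower side, Nrg1, the growth factor neuregulin 1, was at 6.13 ± 2.27 against 9.70 ± 1.48, Crem at 9.60 ± 0.66 against 11.52 ± 0.38, Bst2, an interferon-induced antiviral protein, at 11.37 ± 0.88 against 12.75 ± 0.56, and Arhgef5 at 0, 4.44 and 4.67 against 7.12, 9.15 and 7.40. Mertk had a fold change of -1.07 (SE 0.75), Axl of 0.25 (SE 0.57), Gas6 of 1.26 (SE 0.79), Pros1 of -0.92 (SE 1.73), Ptdss2, the other phosphatidylserine synthase, of 4.13 (SE 1.80) and Lyz2 of 0.12 (SE 0.36), with the signs of Axl, Pros1 and Lyz2 turned by array weights (-0.56, 0.22 and -0.15) and that of Lyz2 also by upper-quartile factors (-0.092). Ptdss1 had a fold change of -2.89 (SE 1.52), which was -0.34 without the knockdown replicate 1 that had 3 reads of it. That of Mertk was -0.36 without the same library, and that of Ptdss2, which had 3.31 in Mertk KO, was 2.05 without control replicate 2 and 0.88 without both low-complexity libraries. Mmp12 was at 1.57 without control replicate 1, and the fold change of Nrg1 went from -3.57 to -2.26 without Ptdss1 knockdown replicate 1.

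Of the 30 lists, 5 passed camera, all toward higher values with the knockdown, and none passed with an estimated correlation (adjusted p = 0.866 with an estimated correlation for each of the 5) or with fry. The list of unfolded protein and amino acid stress (camera adjusted p = 0.00689) had 13 of 17 members positive, with Trib3, a stress-induced pseudokinase, at 6.04 (SE 2.11), the chaperone cofactor Sdf2l1 at 1.22 (SE 0.57), Pdia4 at 1.69 (SE 0.83) and Hyou1 at 2.80 (SE 1.49). The list of inflammatory cytokines (camera adjusted p = 0.00689) had 19 of 24 members positive, with the monocyte chemokine Ccl2 at 1.32 (SE 0.55), Nfkbiz at 1.30 (SE 0.66), the interleukin 1 receptor antagonist Il1rn at 1.04 (SE 0.53) and the lectin Clec4e at 2.45 (SE 1.46). The monocyte list (camera adjusted p = 0.0205) had 12 of 16 members positive, with Ccr2, the receptor for Ccl2, at 2.79 (SE 1.10), F13a1 at 2.80 (SE 1.19), S100a4 at 3.91 (SE 1.98) and Fn1 at 1.07 (SE 0.38). The glycolysis and hypoxia list (camera adjusted p = 0.0205) held Tpi1 at 0.91 (SE 0.41) and Gpi1 at 1.00 (SE 0.49), and the list of immediate early and dissociation genes (camera adjusted p = 0.0495) held Hsph1 at 1.46 (SE 0.67), Egr2 at 1.52 (SE 0.73) and Nr4a1 at 0.86 (SE 0.62). No member of these 5 lists passed the threshold over all genes tested or when adjusted over the list alone. Of the 43 named genes tested in this comparison, 20 had a fold change nearer to 0 by over 1.5 times or of the other sign without Ptdss1 knockdown replicate 1. Among them were Hyou1 at 0.83, Pdia4 at 0.77, Il1rn at 0.40, Egr2 at 0.86, Nr4a1 at 0.13 and Gpi1 at 0.63. S100a4 was at 0.83 and F13a1 at 1.78 without control replicate 2, and Ccl2 and Sdf2l1 were both at 0.69 without control replicate 3. Tpi1 was at 0.60 without Ptdss1 knockdown replicate 3, and Nfkbiz at 1.99 without control replicate 1. With Ptdss1 knockdown replicate 1 left out, 3 lists passed, and of the 5 lists above only the monocyte list was among them. The unfolded protein list then had a camera adjusted p of 0.300, inflammatory cytokines 0.0575, glycolysis 0.197 and immediate early genes 0.690. Other single libraries ended calls too: control replicate 1 for glycolysis (0.964) and immediate early genes (0.116), control replicate 2 for monocyte genes (0.113), control replicate 3 for inflammatory cytokines, monocyte and immediate early genes (0.256, 0.0528 and 0.256), Ptdss1 knockdown replicate 2 for monocyte genes (0.202), Ptdss1 knockdown replicate 3 for inflammatory cytokines, glycolysis and immediate early genes (0.0947, 0.334 and 0.0589), and Mertk KO replicates 1 and 3 for immediate early genes (0.0525 and 0.0603). The other 15 program lists had camera adjusted p between 0.0675 and 0.999, and the 10 cell type lists between 0.569 and 0.999.

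The cell-cycle lists did not pass in this comparison (camera adjusted p = 0.0675 for both, with medians of -0.93 for mitosis and -1.27 for S phase, and adjusted p = 1.00 with an estimated correlation). Leaving out single libraries moved them both ways. At the preset correlation mitosis passed, with lower values in the knockdown, without control replicate 2 (median -2.03, adjusted p = 0.00542), control replicate 3 (0.0491), Mertk KO replicate 4 (0.0487) or Ptdss1 knockdown replicate 2 (median -2.03, adjusted p = 0.00665). S phase passed without control replicate 3 (0.0178), Ptdss1 knockdown replicate 2 (median -2.40, adjusted p = 0.00634) or replicate 3 (median -2.02, adjusted p = 0.0369). Without control replicate 1 the medians were -0.19 and -0.64, and without Ptdss1 knockdown replicate 1 they were above 0, at 0.48 and 0.62. Their means were lowest in Ptdss1 knockdown replicate 1, at 2.04 for mitosis and 3.07 for S phase, against 7.21 and 6.67, and 8.48 and 8.06, in replicates 2 and 3. The centromeric histone Cenpa had a fold change of -2.97 (SE 1.42), the condensin subunit Smc4 of -2.28 (SE 1.22), Cdk1, the mitotic cyclin-dependent kinase, of -3.01 (SE 1.80), Rfc5 of -2.52 (SE 1.34) and the kinase Cdc7 of 4.22 (SE 2.09). Without Ptdss1 knockdown replicate 1 these values were -0.89 for Cenpa, -0.18 for Smc4, -0.47 for Cdk1 and -0.48 for Rfc5.

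The direct comparison of the 2 altered groups tests whether their differences from control differ, since the control cancels. No gene passed the threshold in limma, with a smallest adjusted p of 0.805. An unadjusted limma p below 0.05 was found for 431 genes, where evenly spread p-values would give 578. Voom gave 0 calls on either scaling and 7 with quality weights, array weights gave 35, the covariate and the joint omission of the 2 low-complexity libraries 1 each, and every other setting tried 0. Ccl8, a monocyte chemokine, was at 17.09 ± 0.86 (SD, n = 4) in Mertk KO and 13.65 ± 1.60 (SD, n = 3) in Ptdss1 knockdown, a log2 fold change of 3.44 (SE 0.67, limma adjusted p = 0.805). Fabp5 differed by 2.31 (SE 0.55), Nrg1 by 4.10 (SE 1.00) and Tenm4, a teneurin, by 6.62 (SE 1.66), each higher in Mertk KO. H2-Eb1 had a fold change of -1.22 (SE 0.33) and Gpr183, an oxysterol receptor, one of -5.50 (limma adjusted p = 0.805), while Bex6 and Trim46 were listed at 0 in all 4 Mertk KO libraries. Axl was at 11.15 ± 0.54 (SD, n = 4) in Mertk KO against 12.66 ± 1.35 (SD, n = 3), a difference of -1.51 (SE 0.53, limma adjusted p = 0.805). Mertk differed by 0.75 (SE 0.70), Pros1 by 2.85 (SE 1.62) and Lyz2 by 0.21 (SE 0.33), while the differences of Gas6, Ptdss1 and Ptdss2 (0.12, 1.99 and -0.82) changed sign with array weights (-0.11, -0.51 and 0.15). Without Ptdss1 knockdown replicate 1 the difference of Axl was -0.73, of Mertk 0.036 and of Pros1 0.28. Adjusted over the lists alone, Spp1, Fabp5, Arg1, Chil3, Ecm1, Mgl2 and H2-Eb1 passed, the last 2 with lower values in Mertk KO.

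Of the 30 lists, 2 passed camera in the direct comparison, both with lower values in Mertk KO. The type I interferon list (camera adjusted p = 0.00270, and adjusted p = 0.914 with an estimated correlation) had 28 of 35 members negative, with Irf7, a transcription factor of the interferon response, at -1.72 (SE 0.60), Cmpk2 at -5.44 (SE 1.93) and Phf11d at -1.66 (SE 0.64), while Bst2 was at 1.60 (SE 0.45). The unfolded protein list (camera adjusted p = 0.00270, and adjusted p = 0.717 with an estimated correlation) had 16 of 17 members negative, with Herpud1 at -1.42 (SE 0.57), Trib3 at -4.61 (SE 1.97) and Creld2 at -1.04 (SE 0.57). No member of either list passed over all genes tested or when adjusted over the list alone. Without Ptdss1 knockdown replicate 1 the interferon median went from -0.59 to -0.37 (camera adjusted p = 0.0611) and the unfolded protein median from -0.54 to -0.11 (camera adjusted p = 0.163), with Irf7 at -0.99, Trib3 at -2.93 and Creld2 at -0.67. Without Mertk KO replicate 1, Herpud1 was at -0.92 and Creld2 at -0.63, and the unfolded protein median was -0.36 (camera adjusted p = 0.0167). Without Ptdss1 knockdown replicate 2 that median was -0.999 (camera adjusted p = 0.000361). Of the 31 named genes tested in this comparison, 11 had a fold change nearer to 0 by over 1.5 times or of the other sign without Ptdss1 knockdown replicate 1, and at most 3 without any other library. The mitosis and S phase lists had medians of -0.46 and -0.15 and camera adjusted p of 0.372 and 0.507. Without Ptdss1 knockdown replicate 1 their medians were -2.04 and -1.40, with camera adjusted p of 5.92e-09 and 1.70e-11. Neither passed there with an estimated correlation (adjusted p = 0.375 and 0.205). Both passed with array weights (medians -1.08 and -0.97, camera adjusted p = 1.03e-05 and 1.67e-09). Both also passed with the detected-gene covariate (medians -1.05 and -0.46, camera adjusted p = 0.00927 and 0.0150). Other single libraries turned the medians the other way. They were 0.60 and 0.84 without Ptdss1 knockdown replicate 2, 0.40 and 0.47 without replicate 3, 0.59 and 0.38 without Mertk KO replicate 4, and 0.19 for S phase without Mertk KO replicate 3. The number of lists past camera was 9 without Ptdss1 knockdown replicate 1, 9 without Mertk KO replicate 1 and 6 without Mertk KO replicate 3. The other program lists had camera adjusted p between 0.0748 and 0.997, and the 10 cell type lists between 0.145 and 0.965.

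No gene passed the threshold in the same direction in both comparisons with control, in limma, and 0 would be expected from 2 and 0 calls; array weights gave 2 such genes and every other setting tried gave 0. The fold changes of the 2 comparisons had a correlation of 0.445 across genes, which are not independent replicates, and a covariance of 0.855. Simulated groups without any change that shared their control libraries gave a mean correlation of 0.491 (central 95% of 100 draws, -0.138 to 0.883) and a mean covariance of 1.08 (-0.124 to 2.53), both above the observed values. The share of genes with the same sign was 64.0%, against a simulated mean of 66.7%.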

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

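The tests of marker lists against Spp1 and Fn1 were chosen after the data had been seen. So were the fit with the number of detected genes as a covariate and the joint omission of the 2 low-complexity libraries. Leaving out each library was written in advance. Using the fits without control replicate 1 or Ptdss1 knockdown replicate 1 to weigh an explanation was chosen after the data had been seen. The splits of the libraries were set before their results were seen.

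Within the 4 Mertk KO libraries, 9 of 126 genes, list means and library measures had 1 library far from the other libraries, where chance gives about 1 in 20. The gap of that library to its nearest neighbour, as a share of the range, was 0.854 for the list mean of inflammatory cytokines, highest in Mertk KO replicate 1 (11.43 against 9.83 to 10.06), and 0.866 for the lipid-associated list mean, highest in replicate 4 (12.72 against 12.04 to 12.13). It was 0.915 for Prc1 and 0.84 for Tacc3, both lowest in replicate 3, with 1 and 6 reads. It was 0.832 for Atp6v0d2, lowest in replicate 2, and 0.858 for Bst2, highest in replicate 1. The values of Bst2 spanned only 12.861 to 13.205. Among these 4 libraries Nek3 and Kif4 were read in replicate 2 only, with 1 and 4 reads. Rsc1a1 was read in replicate 4 only, with 88 reads, and the share was 1 for each of these genes.

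Spp1 and Fn1 rose in the libraries labelled Mertk KO, and RNA of fibroblasts that passed the macrophage sort is argued against as the whole cause: Mertk KO replicates 1 and 3, 2 of the 4 libraries, had both genes above every control library while 0 of the 6 tested fibroblast markers (of 12 listed, 0 in another list) lay above the highest control library, with Col1a1 at 1.30 and 1.39. RNA of tumour cells cannot be told apart, because its 6 tested markers (of 17 listed, 0 in another list) went both ways in these 2 libraries. The list mean was no higher than in the highest control library, and Krt18 and Krt7 were at 0 in both. In replicate 3 Krt8 was at 0.86 and Erbb3 at 0, and in replicate 1 Erbb3 was at 1.30. But Krt8 (6.68), Cdh1 (9.81) and Spint2 (5.63) lay above every control library in replicate 1. Cdh1 (10.55) and Spint2 (5.99) did so in replicate 3. Cdh1 was higher in all 4 Mertk KO libraries (9.76 to 10.55) than in control (8.29 to 8.75). Leaving out the 2 low-complexity libraries kept the smaller of the ratios of fold change at 0.951. The limma adjusted p, however, went to 0.169 for Spp1 (3.39, SE 0.59, from 3.23, SE 0.51) and 0.166 for Fn1 (2.12, SE 0.36, from 2.23, SE 0.35), with larger SEs and fewer libraries in the fit. Of the 2 libraries, only control replicate 2 enters these fold changes, which were the same without it alone (3.39 for Spp1 and 2.12 for Fn1). Mertk KO replicates 3 and 4, which also missed commonly detected genes, were kept. The ratio therefore does not test low complexity in the Mertk KO libraries. With the number of detected genes as a covariate the ratio was 1, and low complexity cannot be told apart this way, since that number differed between the groups by 130 genes with an SD of 1541 within groups. Of the 35 splits of these 7 libraries, only the real one gave 2 genes and the highest of the others gave 1. That share is below the 0.05 set for such splits and is the smallest that 35 splits can give. It counts against chance for the number of genes at that level only. With 2 genes against 1 and no correction for the other counts tested by splits, chance is not excluded. An effect of the Mertk knockout, which the design names, stays open and untested. Both genes were also above every control library in all 3 Ptdss1 knockdown libraries.

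The cell-cycle lists lay lower in Mertk KO by camera, and neither call held with an estimated correlation (adjusted p = 0.701 for both) or with fry. The calls depend on control replicate 1, without which the smaller camera adjusted p of the lists was 0.137 and the median over their 83 members went from -1.16 to -0.63, and without Mertk KO replicate 4 the mitosis median went from -1.44 to -0.64. Complexity cannot be told apart with the covariate (ratio 1.12), for the reason given above. In Ptdss1 knockdown, where the lists did not pass, leaving out the low-complexity replicate 1 turned the median from -1.13 to 0.52 (ratio -0.461). Low complexity of that library may account for the lower values there at least in part. With array weights mitosis stayed lower and passed (median -0.32, camera adjusted p = 0.0280), while the S phase median was 0.036. In the joint omission the medians were -0.18 for mitosis and 0.29 for S phase. For the count of lists, 11 of the 35 splits of the Mertk KO and control libraries gave at least the 10 of the real split and the highest of the others gave 14, so chance is not excluded, and an effect of the knockout stays open and untested.

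The type I interferon and unfolded protein lists differed between the altered groups (camera adjusted p = 0.002696 for both), which tests the difference between their effects, but neither call held with an estimated correlation (adjusted p = 0.914 and 0.717) or with fry. Without Ptdss1 knockdown replicate 1 the unfolded protein median went from -0.54 to -0.11 (adjusted p = 0.163), so that low-complexity library may be the source of this call. The interferon median went from -0.59 to -0.37 (adjusted p = 0.0611), and that library as the source of this call cannot be told apart from the smaller fit, since most of the median stayed. Of 35 splits, 32 gave at least the 2 lists of the real one, with a highest other of 13, so chance is not excluded. A difference between the 2 alterations, which the design names, stays open and untested.

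For genes past the threshold in Mertk KO against Ptdss1 knockdown, the real split gave 0, which all 35 splits must reach, so the count of splits decides nothing; the highest of the others gave 1. In Ptdss1 knockdown against control the 10 splits are too few for a share under 0.05. The real split gave 0 genes and the highest of the others 0, so all 10 gave as many, and it gave 5 lists, reached by 5 splits, with a highest other of 11.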

How the results depend on the processing

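Array weights, voom with quality weights or scaled by totals, the detected-gene covariate, the pseudocount of 8, the filter on all libraries, the estimated correlation without Ptdss1 knockdown replicate 1 and the joint omission of the 2 low-complexity libraries were chosen after seeing the data. The planned count models were not run, since the files hold log2 values in place of counts, though whole reads could be recovered from them. With the spread of these data, genes changed 2-fold are below what the test recovers. The cause was not tested where none is given.

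For Mertk KO against control, the 2 genes became 0 with upper-quartile factors, without a filter, with the stricter filter, against a fold of 1.2 and among genes detected in every library, 1 without robust moderation, 4 with quality-weight voom, 25 with array weights, and 0 to 4 on leaving out 1 library. The 2 genes called in the joint omission were Htra1 and Gm10260, not Spp1 and Fn1. For Ptdss1 knockdown, array weights gave 2 genes, Spp1 and Mmp12, both also called in Mertk KO and so 2 shared genes; every other setting tried gave 0. For Mertk KO against Ptdss1 knockdown, array weights gave 35, quality-weight voom 7, and the joint omission and the covariate 1 each. Array weights gave Ptdss1 knockdown replicate 1 a weight of 0.073. Upper-quartile factors shifted the median of all genes by -0.21 for Ptdss1 knockdown against control and by 0.22 for Mertk KO against Ptdss1 knockdown.

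The lists past camera came to 0 in each comparison with an estimated correlation, with all libraries or without Ptdss1 knockdown replicate 1, and with fry. On leaving out 1 library they ranged from 1 to 12 for Mertk KO against control, from 3 to 7 for Ptdss1 knockdown and from 2 to 9 for the direct comparison. Array weights gave 8 lists for the knockdown and 8 for the direct comparison, the joint omission 1 and 8, genes detected in every library 0 and 0, and the covariate 10 for the direct comparison.

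Of 3365 values of 127 results of named genes, where a gene counts once in each comparison that names it, 3287 stayed on their side of the threshold, 27 lost and 21 gained a call, and 30 changed sign; of 355 list values 221, 108 and 16 did so, and 10 turned in camera's direction. Signs changed for Mertk in Mertk KO (-0.67 to 0.19 on leaving out 1 library), Lyz2 (-0.088 with array weights) and Col1a1 (-0.17 to 2.27). In Ptdss1 knockdown they changed for Axl (-0.52 to 0.72; -0.56 with array weights, -0.54 in the joint omission, -0.51 with quality weights), Pros1 (-2.38 to 1.65; 0.22, 0.19 and 0.33), Lyz2 (-0.057 to 0.34; -0.092 with upper-quartile factors, -0.15 with array and -0.031 with quality weights) and Rrm1 (0.18 in the joint omission). In the direct comparison they changed for Gas6 (-0.38 to 0.72; -0.11 with array and -0.22 with quality weights), Ptdss1 (-0.56 to 3.30; -0.51 with array weights, -0.56 in the joint omission, -0.47 with quality weights) and Ptdss2 (-1.48 to 0.36; 0.15, 0.36 and 0.14). The S phase median ran from -2.40 to 0.62 in the knockdown (0.29 in the joint omission) and from -1.40 to 0.84 directly, and the mitosis median from -2.03 to 0.48 and from -2.04 to 0.60 (-0.32 among genes detected in every library, where camera's direction turned and the sign of the median did not).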

Other observations

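In the libraries labelled Mertk KO the MHC class II list had a camera adjusted p of 0.0864, with 9 of 13 members negative, and 2 members passed when adjusted over the list alone in opposite directions: H2-Eb1 at -1.48 (SE 0.33) and H2-DMb2, a chain of the peptide-loading chaperone, at 1.56 (SE 0.51). In the neutrophil list Il1r2 passed alone, at -5.70 (SE 1.59), and in the monocyte list Fn1. In macrophages from tumours with the Ptdss1 knockdown the B cell marker Cd22 passed over its list alone, at -4.19 (SE 1.49), among 3 tested members. Passing over a list alone is not corrected over the lists. Genes of interferon gamma response, sterol synthesis, cholesterol efflux and apoptotic cell uptake had camera adjusted p of 0.201, 0.913, 0.781 and 0.610 in Mertk KO against control.

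A hypothesis set before its test was that a strain segment linked to the Mertk allele may change neighbouring genes. The 164 tested genes within 10 Mb of Mertk on chromosome 2 had a mean absolute moderated t of 0.711. It lay at the 69.0 percentile of 10000 random gene sets matched on expression (median 0.690). Of the 164 genes, 6 had an unadjusted limma p below 0.05, beside 238 of all 11564 genes tested, and none of the 164 passed the threshold. The percentile is below the bound of 95 set for the hypothesis. Missing that bound was set in advance to count against the hypothesis. After the value was seen this rule was changed, and a percentile in the middle range was counted neither for nor against the hypothesis. The power of such a mean over 164 genes was not simulated, so a strain segment cannot be told apart.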
